A study of Arabidopsis thaliana with 12 samples.

How the data were processed

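Messenger RNA was measured in 12-day-old Arabidopsis thaliana seedlings of the wild type (WT, ecotype Col-0) and of a triple mutant in the transcription factor genes WRKY18, WRKY40 and WRKY33. Seedlings were either untreated (0 h) or treated for 2 h with 1 µM flg22, a peptide from bacterial flagellin that the plant receptor FLS2 recognises. Each of the 4 groups held 3 biological replicates, per the labels, which gave 12 libraries. The untreated seedlings were sampled at 0 h, and no mock treatment of 2 h was analysed here, so a flg22 comparison also spans the 2 h between the samplings and any handling that went with the treatment.

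Libraries were made from polyadenylated RNA with a stranded kit, per the labels' protocols. FastQC 0.11.2, TopHat2 2.0.10, HTSeq and the TAIR10 genome build were named per the submitters' processing notes, which gave no version for HTSeq. The authors deposited a table of raw read counts per gene, with 1 column per library and no normalization. The strand setting of the counting and the annotation release were not given in the sources used here, so reads of overlapping genes on opposite strands were treated as uncertain. The table also held 5 summary rows that name no gene, such as reads outside genes and reads aligned to several places. Those rows took 8.15% to 19.9% of the reads in a library and were left out of library sizes and tests. Because reads aligned to several places were set apart from the counts, genes with near-identical copies may be undercounted.

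The table listed 32678 gene identifiers, of which 7363 had 0 reads in all 12 libraries, and 97.7% of the identifiers matched an entry of the TAIR10.1 reference annotation. Gene symbols and positions were taken from that annotation. Reads in genes ranged from 20.0 M to 29.8 M per library. Genes were filtered with filterByExpr of edgeR by group, which left 20710 tested genes, and libraries were scaled with TMM factors. Counts per M (CPM) were computed from the deposited counts with these factors. TMM assumes that most genes do not change, and the factors were 1.19 ± 0.0139 (SD, n = 3) in untreated WT against 0.845 ± 0.00964 in flg22-treated WT. In the triple mutant the factors were 1.19 ± 0.0313 before and 0.833 ± 0.0102 after flg22. Differences between time points are therefore relative to the middle of the fold change distribution.

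The main test was the quasi-likelihood F-test of edgeR 4.0.16 in R 4.3.3 on all 12 libraries, with a mean per group and no replicate block. The 5 contrasts were flg22 in WT, flg22 in the mutant, genotype in untreated seedlings, genotype after flg22, and the genotype by flg22 interaction. P-values were adjusted with the Benjamini-Hochberg method over all tested genes, and 0.05 was the threshold. Genes that also changed at least 2-fold were counted beside these. Standard errors (SE) were derived from the log2 fold change and the F statistic. A fold change against a group with no reads was given as a bound, computed against 3 counts over the group, and such bounds and intervals cover counting error only. The p-values rest on the spread between biological replicates, estimated over all 4 groups together.

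The lists of genes, 26 with 363 members, were drawn from textbook knowledge. The 3 mutated genes formed 1 of them and were reported singly. The other 25 were tested with camera in limma 3.58.1 on log2 CPM with a prior count of 2 and a preset correlation of 0.01 between genes, for lists with at least 5 tested members. P-values were adjusted over the 25 lists. The same test with an estimated correlation, and the fry test, which asks whether a list's genes move one way on balance, were run as alternatives. Of the listed genes, 353 were tested.

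Genes named in the text followed a rule. It took the mutated genes, then per contrast the 6 genes with the largest rise and the 6 with the largest fall among those past the threshold with a mean of at least 5 CPM in a compared group and the same direction in all 3 replicate numbers. It also took up to 4 members per list with the largest change past the threshold. IREG1, AT2G38450, AT4G31805 and AT2G38430 met this rule, and the other genes beside the mutated loci, such as AT2G38465, SCAR2 and CIPK22, were chosen after their values were seen. Not all genes that met the rule are named in the text, and 1 gene with an interaction is among those not reported. The grouping, tests, lists, naming rule and most alternatives were fixed before the data were examined.

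The alternatives were DESeq2 1.42.0, RLE size factors, no filter on low counts, a stricter filter of at least 1 CPM in at least 6 libraries, fits of only the compared groups, the replicate number as a block, and leaving out each library in turn. Scaling by total reads, scaling by 7 reference genes, and a fit without 2 libraries that stood apart were added after the data were seen. The procedure was tested on simulated counts with 50 changed genes at each fold size in each contrast. For the WT flg22 contrast, run on 20522 genes, 44% of the genes changed 1.5-fold, 72% of those changed 2-fold and 90% of those changed 4-fold were recovered. For the interaction, run on 20620 genes, the shares were 18%, 52% and 72%. The WT flg22 run made 5 false calls and the interaction run 7. All other genes were left unchanged in the simulated contrast, whereas 71.7% of tested genes changed with flg22 in WT. The recovered shares therefore may not hold for the flg22 contrasts. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.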

Results

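The data comprised 12 RNA-seq libraries from 12-day-old Arabidopsis seedlings, with 3 biological replicates of each of 4 groups. The groups were untreated WT, WT after 2 h with 1 µM flg22, the untreated wrky18 wrky40 wrky33 triple mutant, and the triple mutant after the same treatment. Reads in genes averaged 26.0 M ± 2.75 (SD, n = 3) in untreated WT and 23.4 M ± 4.28 in flg22-treated WT. They averaged 27.3 M ± 3.05 in the untreated mutant and 23.4 M ± 2.95 in the treated mutant. The first principal component held 85.1% of the variance and separated untreated from treated libraries, and the second held 4.61% and separated the mutant libraries from WT. Replicates of a group correlated across genes at 0.984 to 0.993 on the log scale, and all 12 replicate pairs differed by more than sampling noise, with chi-square per degree of freedom of 3.13 to 24.1. Replicate 2 of the untreated mutant lay apart from its group on the second component, at 41.2 against 19.2 and 20.8. Untreated WT was also spread on this component, at -25.2, -35.9 and -9.96 for replicates 1, 2 and 3. On the first component untreated mutant replicates 1, 2 and 3 lay at -95.53, -80.33 and -96.35. Those of untreated WT lay at -112.3, -119.1 and -105.3. The highest chi-square, 24.1, was that of replicates 2 and 3 of treated WT. Replicate 3 of the treated mutant had 16.2% of reads aligned to several places and 1.14% of gene reads from the chloroplast, against at most 7.98% and 0.501% in the other libraries of its group.

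The mutated genes were examined first in every library. WRKY18 (AT4G31800) lies on chromosome 4 at 15382777 to 15385100, WRKY40 (AT1G80840) on chromosome 1 at 30383561 to 30385499 and WRKY33 (AT2G38470) on chromosome 2 at 16108235 to 16110766 (TAIR10.1). In WT, WRKY40 rose 67.8-fold after flg22, from 10.5 ± 2.15 to 714 ± 26.2 CPM (SD, n = 3), and WRKY33 rose 32.8-fold, from 49.6 ± 11.7 to 1630 ± 127 CPM. WRKY18 rose 2.48-fold, from 24.5 ± 6.79 to 60.9 ± 14.8 CPM. In the untreated mutant, WRKY18 gave 3.69, 3.94 and 4.74 CPM in the 3 libraries and WRKY40 gave 1.88, 1.16 and 1.27 CPM, which were 5.94-fold and 7.38-fold below WT. WRKY33 reads were not lower in the untreated mutant, at 57.8, 60.6 and 59.1 CPM (log2 fold change 0.25 ± 0.13 SE, adjusted p = 0.249). After flg22, WRKY33 gave 164, 155 and 178 CPM in the mutant against 1570, 1540 and 1770 CPM in WT, a 9.81-fold difference. WRKY40 gave 20.2, 20.9 and 30.3 CPM in the treated mutant and 717, 738 and 686 CPM in treated WT, a 29.9-fold difference. WRKY18 gave 9.53, 11.2 and 17.2 CPM in the treated mutant against 53.0, 78.0 and 51.8 CPM in WT, a 4.80-fold difference. WRKY18 and WRKY40 were thus below every WT library of the same time in each mutant library, and WRKY33 was so only after flg22. The counts do not show whether the remaining reads came from intact transcripts.

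**Figure D1:**
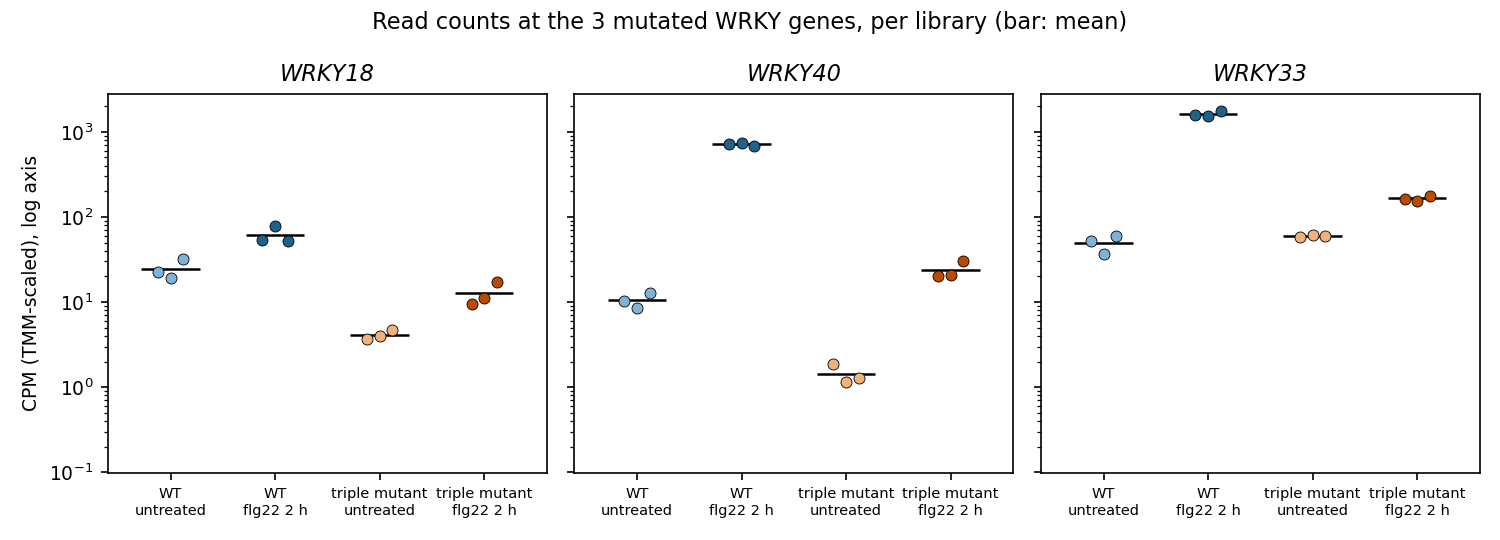
Counts per M (TMM-scaled, log axis) of WRKY18, WRKY40 and WRKY33 in each of the 12 libraries, with a bar at each group's mean. After flg22, WRKY40 averaged 714 CPM in WT and 23.8 CPM in the triple mutant, and WRKY33 averaged 1630 and 166 CPM, whereas untreated WRKY33 averaged 49.6 and 59.2 CPM.

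The response of WT seedlings to flg22 covered defence signalling and specialised metabolism. The peroxidase gene PER4, an early flg22 marker, rose from 2.67 ± 0.223 to 875 ± 51.2 CPM (n = 3, log2 fold change 8.36 ± 0.15 SE, adjusted p = 2.56e-14). PROPEP3, which encodes the precursor of a danger peptide, rose from 0.954 ± 0.186 to 227 ± 53.0 CPM (log2 fold change 7.88). IGMT2, a methyltransferase of indole glucosinolates, rose from 11.1 ± 3.27 to 1360 ± 43.0 CPM (log2 fold change 6.95). The strongest falls included the microRNA gene MIR167d, from 11.8 ± 0.37 to 0.0677 ± 0.0609 CPM (log2 fold change -7.34), and AT4G38860, a SAUR-like auxin-responsive gene, from 13.4 ± 2.28 to 0.139 ± 0.0667 CPM (-6.57). The flavonol regulator MYB111 (-5.79), the cytochrome P450 gene CYP96A9 (-5.62), the gibberellin methyltransferase gene GAMT2 (-5.52) and AT3G09450 (-6.80) fell as well. Other large rises were those of the cytochrome P450 gene CYP82C3, from 0.484 ± 0.0293 to 185 ± 15.2 CPM (8.57), and of the lipase gene AT4G16820 (8.75). The germin-like gene GLP6 reached 8.05 CPM from 0.00962 CPM, and AT1G02190 15.8 CPM from 0.0337 CPM. AT2G13640 and the pseudogene AT1G19030 had no reads in untreated WT and were at least 216-fold and at least 170-fold higher after flg22.

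All 25 measured genes of pattern receptors and early signalling rose, with a median log2 fold change of 3.04, including PROPEP2 (7.67), MPK11 (5.99) and the ubiquitin ligase gene PUB23 (5.88). All 9 flg22 marker genes rose (median 5.09), among them NHL10 (6.81) and CYP81F2 (6.24). The same held for all 10 genes of secretion and penetration resistance (median 3.49), such as MLO6 (5.85) and SYP122 (5.14), and for all 5 touch response genes (median 3.34). Of 29 other WRKY genes, 25 rose and 2 fell (median 3.09), led by WRKY30 (6.76), WRKY41 (6.29) and WRKY75 (5.88). Of 10 camalexin genes, 9 rose (median 4.96), including the transporter gene ABCG40 (6.60) and PAD3, the last enzyme of the pathway (6.18). Of 17 indole glucosinolate genes 13 rose and 2 fell (median 2.88), and of 20 ethylene genes 16 rose and 4 fell (median 1.71), with ERF6 at 5.47 and the ACC synthase gene ACS2 at 5.18. Each of these lists had adjusted p = 0.235 with an estimated correlation, against 0.000931 to 2.56e-12 apart from touch response (0.00202) with the preset correlation of 0.01.

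Of 26 jasmonate genes, 21 rose and 3 fell (median 2.18, adjusted p = 0.248 with an estimated correlation), including LOX4 (5.19) and CYP94C1 (4.99). Tryptophan biosynthesis rose in 7 of 8 genes and fell in 1 (median 3.79), with ASA1 at 4.75, and phenylpropanoid and lignin genes rose in 11 of 13 and fell in 1 (median 2.16), with CCR2 at 6.03 and PAL1 at 3.27. Both had adjusted p = 0.262 with an estimated correlation. Among calcium genes 10 of 12 rose and 1 fell (median 1.04, adjusted p = 0.273 with an estimated correlation), led by CML37 (6.99) and the calcium pump gene ACA12 (6.81). Salicylic acid genes rose in 15 of 20 cases and fell in 1 (median 1.79), with CBP60g at 4.6 and EDS5 at 3.28. Cysteine-rich receptor kinases rose in 8 of 12 cases and fell in 1 (median 1.87), with CRK20 at 6.67. NLR genes, a class of intracellular immune receptors, rose in 11 of 12 cases (median 1.67), with ZAR1 at 2.94. These 3 lists had adjusted p = 0.322 with an estimated correlation. Genes of protein folding in the endoplasmic reticulum (ER) rose in 8 of 11 cases (median 0.76, adjusted p = 0.345 with an estimated correlation), with BIP3 at 4.58 and bZIP60 at 3.04. Every list of this paragraph passed camera with the preset correlation, at adjusted p from 2.5e-06 (jasmonate) to 0.00373 (cysteine-rich receptor kinases). Each also passed by fry.

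Of 12 aliphatic glucosinolate genes, 10 fell and 1 rose (median -1.27, adjusted p = 0.345 with an estimated correlation), including the regulator MYB28, from 41.1 ± 3.01 to 5.46 ± 0.26 CPM, while the sulfotransferase gene SOT17 rose (2.79). Flavonoid genes fell in 8 of 11 cases (median -1.25, adjusted p = 0.262 with an estimated correlation), with chalcone synthase (CHS) at -2.33. Nuclear photosynthesis genes fell in 15 of 21 cases and rose in 1 (median -0.31, adjusted p = 0.477 with an estimated correlation), with RBCS1B at -1.73 and PSAD1 at -1.46. Cell cycle genes fell in 7 of 10 cases (median -0.71, adjusted p = 0.542 with an estimated correlation), with TSO2 at -1.88 and PCNA1 at -1.75, and this call was lost without replicate 2 of treated WT (adjusted p = 0.0785). The abscisic acid list held 6 rises and 3 falls among 14 genes, such as ABI5 (3.29) and RD29A (-3.16), and the auxin list 5 rises and 6 falls among 13, such as IAA19 (2.50) and IAA3 (-3.18). The circadian clock list held 5 rises and 4 falls among 13 genes, with TOC1 at 1.99 and GRP7 at -1.78, and root markers held 1 rise and 4 falls among 13. Reference genes held 2 rises and 2 falls among 7, with UBQ10 at 1.48 and EF1A at -0.60. These last 5 lists did not pass camera with the preset correlation (adjusted p = 0.575 to 0.714). The clock list had a median of -0.07 but a mean of 0.11. Camera looks for a common direction, so it cannot judge lists whose genes moved both ways. By fry, abscisic acid (adjusted p = 0.0105) and reference genes (2.78e-05) passed. Tested without regard to direction, fry gave these 5 lists unadjusted p from 7.9e-13 (auxin) to 5.86e-07 (reference genes). Adjusted over the list alone, the counts were the same in every list except root markers, where 3 genes fell.

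In total, 14858 of 20710 tested genes (71.7%) changed in WT, 6964 higher and 7894 lower, by edgeR's quasi-likelihood test. At least 2-fold changes were found for 3991 higher and 3604 lower genes. Which direction held more genes depended on the method, with 7505 higher and 7235 lower by RLE factors and 7646 and 7163 by DESeq2. Scaling by total reads moved the median log2 fold change by -0.495 and gave 4513 higher and 12152 lower genes (2862 and 6672 at 2-fold), and scaling by reference genes moved it by -0.235 and gave 5582 higher and 9977 lower (3389 and 4871 at 2-fold). By total reads the median of the abscisic acid list went from 0.02 to -0.48 and that of the reference genes from 0.07 to -0.43, and the clock list went from -0.07 to 0.01 with RLE factors. By total reads 8 abscisic acid genes, 8 clock genes, 9 root markers, 5 reference genes, 4 salicylic acid genes and 3 ER folding genes fell, and 3 auxin and 3 clock genes rose. Salicylic acid genes fell in 2 and 4 cases without untreated replicates 1 and 2. Photosynthesis genes rose in 2 cases without treated replicate 1. Clock genes fell in 2 cases without untreated replicate 3, as did root markers without that library or treated replicates 2 or 3. Root markers rose in 3 cases with RLE factors and without treated replicate 3, and in 2 without untreated replicate 3 or treated replicate 1. The flavonoid list lost its call by total reads (adjusted p = 0.068), and the cell cycle list by total reads (0.105) and by reference genes (0.0535). Reads outside genes took 2.94% ± 0.292 of the reads in treated WT against 1.65% ± 0.0911 in untreated WT.

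The triple mutant was treated in the same way to ask how far the flg22 response depends on the 3 WRKY factors. Its response resembled that of WT in extent. PER4 rose from 3.12 ± 0.745 to 818 ± 54.8 CPM (n = 3, log2 fold change 8.03 ± 0.15 SE, adjusted p = 3.4e-14), WRKY30 from 1.70 to 229 CPM (7.06), and IGMT2 from 15.8 ± 4.76 to 1750 ± 120 CPM (6.79). Among the largest rises were AT2G31345 (8.63), the peroxidase gene AT1G14550 (7.85) and the NAC transcription factor gene AT3G12910 (7.77). AT5G22670 reached 9.63 CPM from 0.00988 CPM and AT1G06135 7.43 CPM from 0.0213 CPM. The largest falls included AT4G38860 (-6.52), MIR167d (-6.33), WRKY49 (-5.39), GAMT2 (-5.22), AT1G19900 (-5.20) and CYP707A2, an abscisic acid hydroxylase gene (-4.94).

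Pattern receptor and early signalling genes rose in 24 of 25 cases in the mutant (median 2.60), with PROPEP3 at 7.08 and PUB22 at 5.18, and all 9 flg22 markers (median 3.80), all 10 secretion genes (3.19) and all 5 touch genes (2.13) rose. Camalexin genes rose in 9 of 10 cases and fell in 1 (3.92), other WRKY genes rose in 24 of 29 and fell in 2 (2.46), and indole glucosinolate genes rose in 13 of 17 and fell in 3 (2.78). Jasmonate genes rose in 19 of 26 cases and fell in 2 (1.82), tryptophan genes rose in 7 of 8 and fell in 1 (3.70), and flavonoid genes fell in 8 of 11 (-1.09). All of these lists had adjusted p = 0.264 with an estimated correlation. Ethylene genes rose in 13 of 20 cases and fell in 6 (1.02, adjusted p = 0.272 with an estimated correlation), and aliphatic glucosinolate genes fell in 11 of 12 and rose in 1 (-1.49, adjusted p = 0.35 with an estimated correlation). Phenylpropanoid genes rose in 10 of 13 cases and fell in 1 (1.83, adjusted p = 0.37 with an estimated correlation). Calcium genes rose in 9 of 12 cases and fell in 2 (0.81), cysteine-rich receptor kinases rose in 8 of 12 and fell in 1 (1.24), and NLR genes rose in 10 of 12 and fell in 1 (1.34), each with adjusted p = 0.379 with an estimated correlation. ER folding genes rose in 8 of 11 cases (0.89, adjusted p = 0.396 with an estimated correlation), salicylic acid genes rose in 13 of 20 and fell in 5 (1.32, adjusted p = 0.439 with an estimated correlation), and photosynthesis genes fell in 14 of 21 and rose in 1 (-0.31, adjusted p = 0.501 with an estimated correlation).

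The lists of cell cycle genes (3 of 10 fell, but 9 by total reads, 6 by reference genes and 7 without untreated replicate 2), abscisic acid (5 rose and 5 fell of 14), auxin (5 and 5 of 13), the clock (5 and 6 of 13), root markers (2 and 3 of 13) and reference genes (2 and 2 of 7) did not pass in the mutant (adjusted p = 0.212 to 0.901), but the cell cycle list passed without untreated replicate 2 (0.0271). These were camera results, which cannot judge lists whose genes moved both ways. By fry, the cell cycle list (adjusted p = 0.0484) and the reference genes (2.5e-05) passed. The clock list had a median of -0.34 and a mean of 0.05, and the auxin list a median of 0.02 and a mean of -0.13. Adjusted over the list alone, 25 other WRKY genes rose, 7 clock genes fell and 2 root markers fell, and the other counts were the same. In total 14651 genes changed in the mutant, 6868 higher and 7783 lower, of which 3735 and 3392 changed at least 2-fold. More were higher by RLE factors (7264 against 7144 lower) and by DESeq2 (7418 against 7068). Scaling by total reads gave 4262 higher and 12420 lower genes (2477 and 6745 at 2-fold) with a median shift of -0.517, and scaling by reference genes 5493 and 9939 (3071 and 4668 at 2-fold) with a shift of -0.232. The medians of the abscisic acid, auxin and reference gene lists went from 0.11, 0.02 and 0.07 to -0.40, -0.49 and -0.45 by total reads, and the flavonoid list lost its call with total reads (adjusted p = 0.0621). By total reads 8 abscisic acid genes, 7 root markers, 5 reference genes and 3 genes each of phenylpropanoids, cysteine-rich receptor kinases and ER folding fell. Without untreated replicate 2 salicylic acid and clock genes fell in 3 cases each, without treated replicate 3 in 2 and 3, and without treated replicate 1 salicylic acid genes in 3. Root markers fell in 5 cases without untreated replicate 3. The 2 responses shared 12939 changed genes, against 10511 for independent lists, and 99.8% of the shared genes changed in the same direction. Their log2 fold changes correlated at 0.946 across genes, which are not independent replicates.

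**Figure D2:**
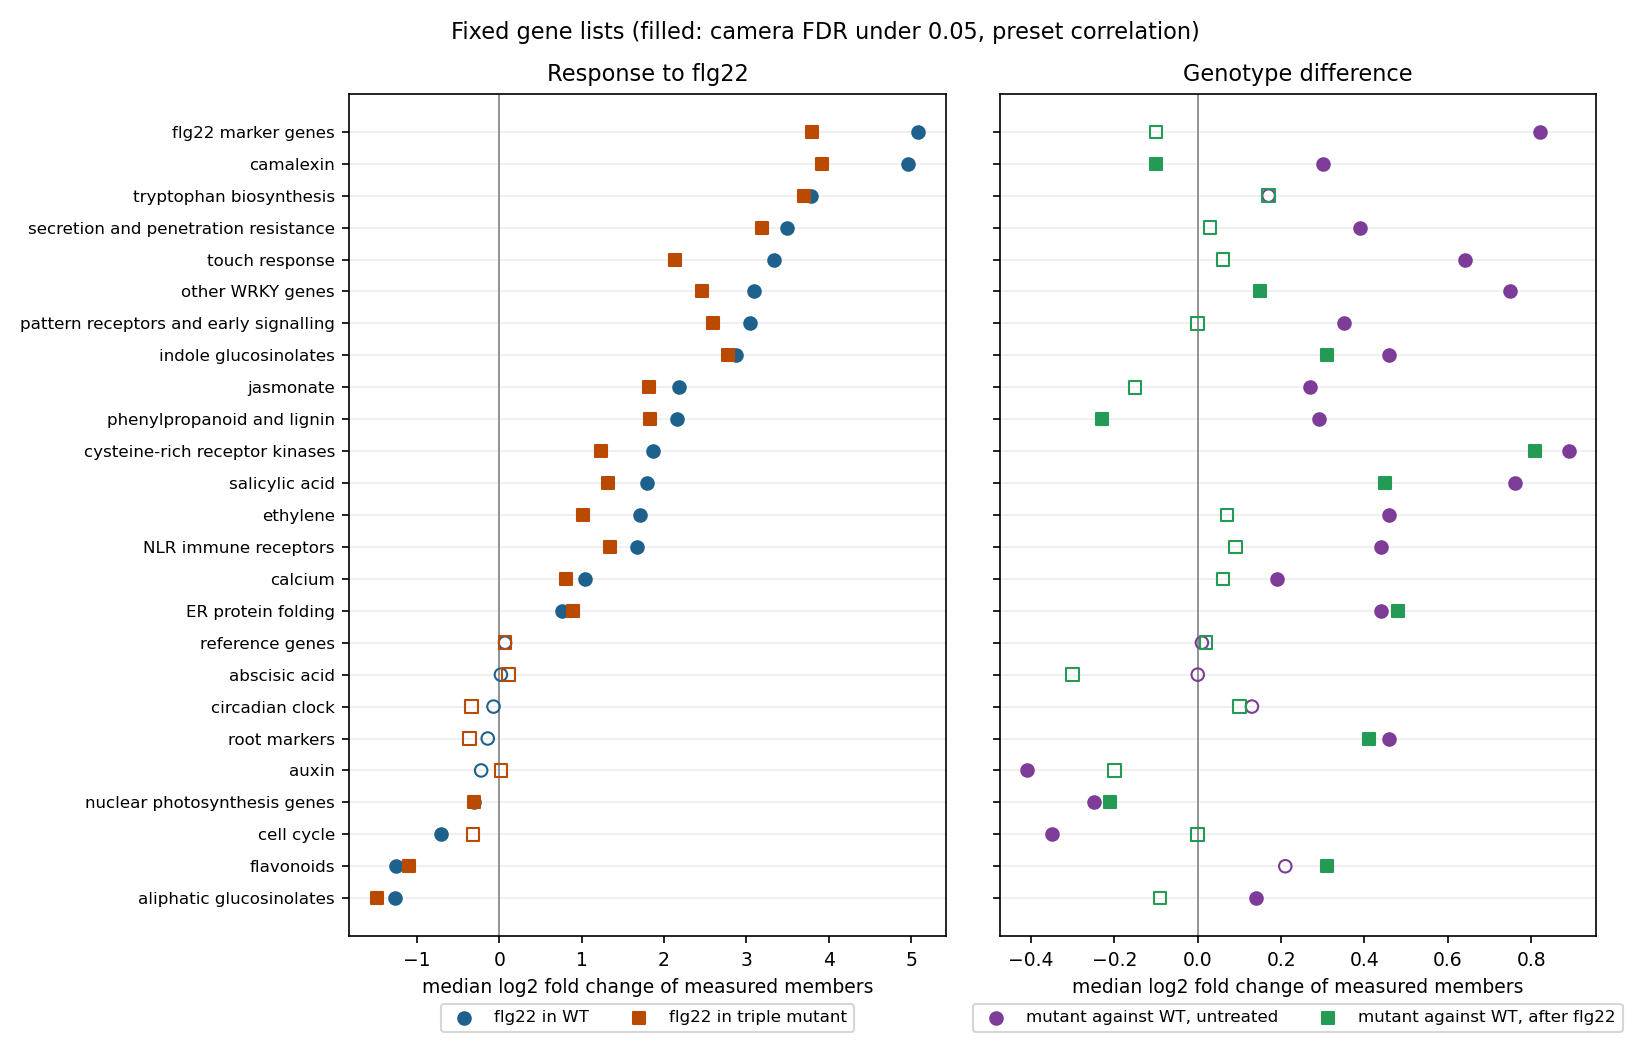
Median log2 fold change of the measured members of 25 gene lists, for the flg22 response in WT and in the triple mutant (left) and for the mutant against WT before and after flg22 (right), with filled symbols for lists past an adjusted p of 0.05 at the preset correlation. The flg22 marker genes had medians of 5.09 in WT and 3.80 in the mutant, and their genotype difference was 0.82 in untreated seedlings and -0.10 after flg22, while scaling changed the sign of the abscisic acid and reference gene medians in both flg22 responses, of the clock median in WT and of the auxin median in the mutant, and the untreated abscisic acid median lay between -0.01 and 0.01.

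Untreated seedlings of the 2 genotypes were compared to show what the mutant differed in before treatment. PR2, a glucanase gene and salicylic acid marker, was at 196 ± 40.9 CPM against 10.1 ± 9.63 in WT (SD, n = 3, log2 fold change 4.25 ± 0.56 SE, adjusted p = 0.000451), and PR1 was at 51.1 ± 8.37 against 5.91 ± 8.20 (3.07 ± 0.66, adjusted p = 0.00992). WT replicate 3 stood apart in both, at 21.2 CPM of PR2 against 4.67 and 4.40, and at 15.4 CPM of PR1 against 1.09 and 1.26. Without it both log2 fold changes were 5.43. PR5 was at 72.2 ± 11.9 against 15.0 ± 7.17 CPM (2.26), and the ER chaperone gene BIP3 at 12.6 ± 1.85 against 1.12 ± 0.20 CPM (3.48). The defensin gene PDF1.2a was at 3.35 ± 0.977 against 0.064 ± 0.0282 CPM (5.60), and the amylase gene AMY1 (4.36), MAF5 (4.00) and AT1G58225 (4.46) were also higher. MRD1 was at 34.3 ± 2.14 against 0.617 ± 0.337 CPM (5.79), a value that is uncertain because MRD1 overlaps HEI10 on the opposite strand and the strand setting of the counting was not given. The protochlorophyllide oxidoreductase gene PORA was lower (-1.64), a call lost without either of 2 libraries (adjusted p up to 0.0986, without WT replicate 2). RD29A, a gene of the abscisic acid and cold response, was also lower, at 38.6 ± 3.51 against 97.9 ± 6.03 CPM (-1.34, adjusted p = 8.93e-06).

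Of 29 other WRKY genes, 16 were higher in the untreated mutant (median 0.75), and adjusted over the list alone 18 were higher and 1 lower, with WRKY46 at 1.5 and WRKY70 at 1.43. Among 20 salicylic acid genes 13 were higher (median 0.76), or 16 higher and 1 lower adjusted over the list alone. Among 12 cysteine-rich receptor kinases 8 were higher (median 0.89), or 11 adjusted over the list alone, including CRK4 (2.75), CRK7 (2.36) and CRK36 (2.19). Pattern receptor genes were higher in 10 of 25 cases (median 0.35), or 16 adjusted over the list alone, with RLP23 at 2.31 and SOBIR1 at 0.99. The flg22 markers were higher in 4 of 9 cases (0.82; 5 adjusted over the list alone), with ATL2 at 1.05, and ER folding genes in 8 of 11 (0.44; 11 adjusted over the list alone). Ethylene genes were higher in 8 of 20 cases (0.46), or 10 higher and 1 lower adjusted over the list alone, with ERF1 at 1.35 and ERF6 at 1.25. Touch genes were higher in 3 of 5 cases (0.64), or 4 adjusted over the list alone, and auxin genes were lower in 4 of 13 (-0.41), or 7 adjusted over the list alone, with IAA3 at -0.99. All of these lists had adjusted p = 0.173 with an estimated correlation, and 0.000792 or less with the preset one. Without WT replicate 2 the counts were 9 other WRKY genes, 5 pattern receptor genes, 3 ER folding genes, 1 touch gene and 1 auxin gene. They were 10, 5, 4, 1 and 1 without mutant replicate 2. Other WRKY genes numbered 10 and touch genes 1 without WT replicate 1, and auxin genes 7 without WT replicate 3.

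Smaller groups followed. Photosynthesis genes were lower in 6 of 21 cases (median -0.25; 11 adjusted over the list alone), with LHCB2.2 at -0.53. Indole glucosinolate genes were higher in 5 and lower in 1 of 17 cases (0.46), or 10 and 1 adjusted over the list alone, and phenylpropanoid genes were higher in 6 of 13 by either count (0.29), with CCR2 at 1.12 and PAL3 at 0.85. These 3 lists had adjusted p = 0.245 with an estimated correlation. NLR genes were higher in 6 of 12 cases (0.44; 7 adjusted over the list alone; adjusted p = 0.253 with an estimated correlation), with ADR1 at 0.83 and ADR1-L2 at 0.82. Calcium genes were higher in 3 of 12 by either count (0.19), with CML41 at 2.02, secretion genes in 5 of 10 (0.39; 7 adjusted over the list alone) and root markers in 1 of 13 (0.46; 6 higher and 1 lower adjusted over the list alone), each with adjusted p = 0.353 with an estimated correlation. Camalexin genes were higher in 3 of 10 cases (0.30; 4 higher and 1 lower adjusted over the list alone) and cell cycle genes were lower in 1 of 10 (-0.35; 3 adjusted over the list alone), both with adjusted p = 0.389 with an estimated correlation. Jasmonate genes were higher in 3 of 26 cases (0.27; 6 higher and 3 lower adjusted over the list alone; adjusted p = 0.456 with an estimated correlation), and aliphatic glucosinolate genes in 3 of 12 by either count (0.14; adjusted p = 0.501 with an estimated correlation), with MAM3 at 0.74. The call was lost without any 1 of 4 libraries for aliphatic glucosinolates (adjusted p up to 0.252, without mutant replicate 1), as it was with no filter (0.102) and by total reads (0.0617), and of 3 for root markers (up to 0.131, without mutant replicate 2). It was lost without either of 2 libraries for jasmonate (up to 0.118, without mutant replicate 2) and camalexin (up to 0.0849, without WT replicate 1), and without mutant replicate 2 for the cell cycle (0.0963). Without both libraries that stood apart it was lost for jasmonate and root markers (0.114 each), camalexin (0.0536) and the cell cycle (0.0986). Without 1 library the counts moved as follows. Photosynthesis genes numbered 2 without WT replicate 2 and 3 without WT replicate 1 or any mutant library. Phenylpropanoid genes numbered 3 without WT replicate 2 or mutant replicate 2, and secretion genes 0 and 1. Without WT replicate 1, WT replicate 2 or mutant replicate 2 there were 3 indole glucosinolate genes, 1 camalexin gene, 1 jasmonate gene, no root marker, no clock gene and no cell cycle gene. Without WT replicate 3 there were 8, 6 and 7 of the first 3 and 4 clock genes. Aliphatic glucosinolate genes numbered 1 without WT replicate 1 or 2, cell cycle genes 4 without mutant replicate 1 and 0 without replicate 3, and root markers 6 without mutant replicate 3. The lists of tryptophan biosynthesis (0 of 8; 2 higher and 1 lower adjusted over the list alone), flavonoids (0 of 11 by either count), abscisic acid (1 higher and 1 lower of 14; 2 and 1 adjusted over the list alone), the clock (1 of 13; 3 adjusted over the list alone, and 3 with RLE factors) and reference genes (0 of 7 by either count) did not pass (adjusted p = 0.0758 to 0.97). The clock list passed without WT replicate 3 (adjusted p = 0.00214). By fry, jasmonate, camalexin, aliphatic glucosinolates, the cell cycle and root markers did not pass (adjusted p = 0.0708 to 0.164).

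In total 2218 genes differed between the untreated genotypes, 1542 higher and 676 lower in the mutant, of which 397 and 83 differed at least 2-fold. The count was 945 without mutant replicate 2, 1143 without WT replicate 1 and 902 without WT replicate 2. Of the genes that differed, 1841 also changed with flg22 in WT, against 1591 for independent lists, and 87% of these went the same way. For 1085 genes, higher in the mutant went with a rise after flg22 (519 if independent), and for 516 lower went with a fall (258 if independent). The log2 fold changes of both comparisons correlated at 0.397 across genes with a covariance of 0.301. Both comparisons share the untreated WT libraries, and simulated unchanged groups against these gave a correlation of 0.465 and a covariance of 0.033, at most 0.036 in 20 runs, with 0 shared calls. The covariance exceeded the simulated mean by 0.268. Splitting 3 control libraries leaves a part with fewer than 2, so part of the excess in shared calls may come from the shared controls.

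Genes beside 2 of the mutated loci had almost no reads in the mutant. IREG1, a metal transporter gene on chromosome 2 at 16103164 to 16106208, had 730 reads in the 6 WT libraries and 1 read in the 6 mutant libraries. Its neighbours AT2G38450 and AT2G38465 had 1797 and 316 reads in WT and 7 and 2 in the mutant. AT2G38465 and SCAR2 were chosen after their values were seen. AT4G31805, which starts 180 bp from the end of WRKY18, had 680 reads in WT and 2 in the mutant, counts left uncertain by AT4G31810, which overlaps its end on the opposite strand. After flg22, IREG1 and AT4G31805 had no reads in the mutant, at least 33.0-fold and at least 47.8-fold below WT. Over both times the ratio of WT to mutant was 263 for AT2G38450 (exact conditional 95% interval 127 to 655, counting error only), 748 for IREG1 (134 to 29600), 162 for AT2G38465 (44.4 to 1340) and 348 for AT4G31805 (96.0 to 2880). SCAR2, the next gene beyond AT2G38450, did not pass the test, with log2 fold changes of -0.01 ± 0.08 and -0.03 ± 0.08 (SE). AT2G38430, beyond SCAR2 and overlapping it on the opposite strand, which leaves its count uncertain, was higher in the mutant, at 48.0 ± 14.7 against 1.01 ± 0.239 CPM after flg22.

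**Figure D3:**
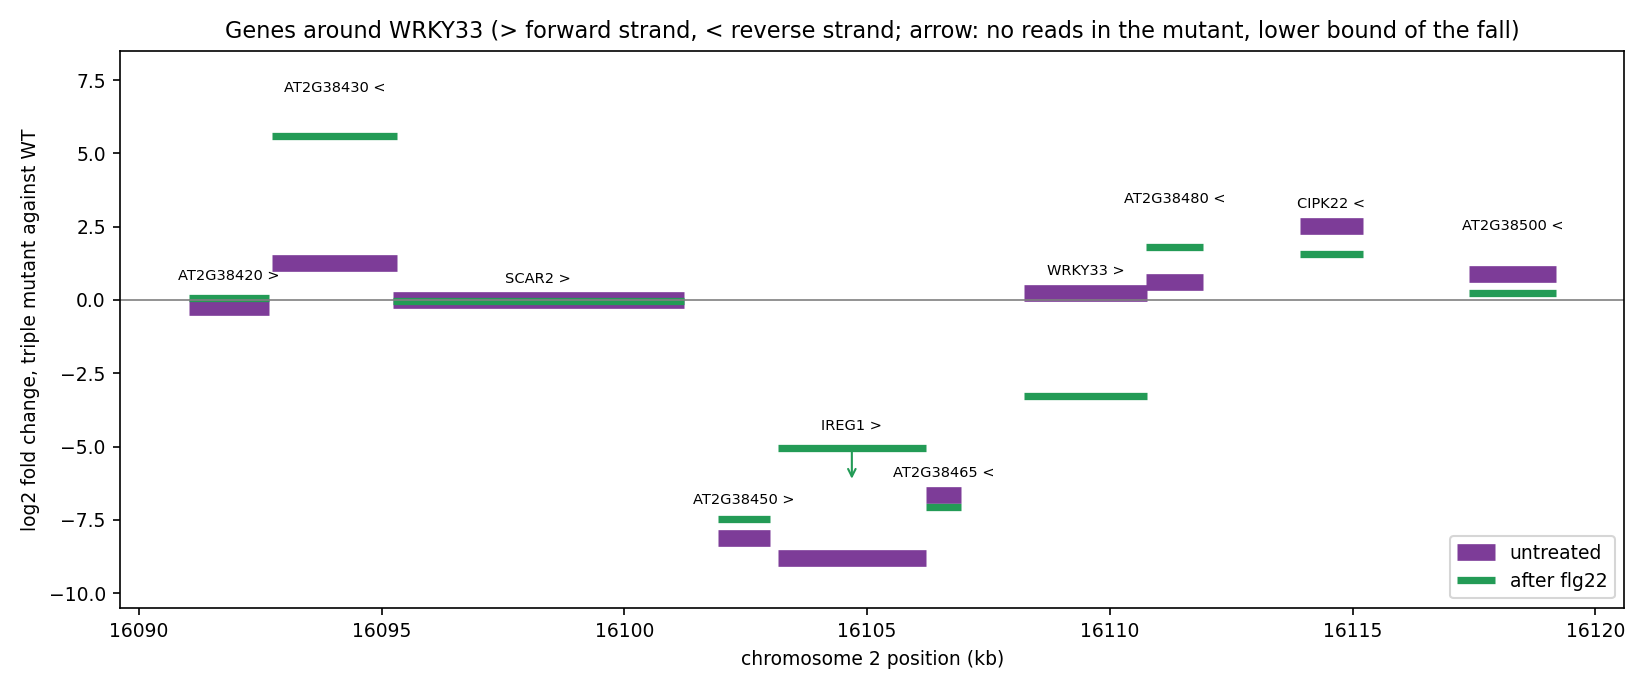
Map of chromosome 2 around WRKY33 (TAIR10.1 position in kb) with the fitted log2 fold change of the mutant against WT for each tested gene, untreated (thick purple lines) and after flg22 (thin green lines). AT2G38450, IREG1 and AT2G38465 lay far below 0, with 7, 1 and 2 reads in the 6 mutant libraries, so the value of IREG1 in untreated seedlings rests on 1 mutant read, and IREG1 after flg22 is drawn at its bound of at least 33.0-fold.

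The genotypes were also compared after flg22. CYP71A13, an enzyme of camalexin synthesis with a close copy in CYP71A12, was at 0.605 ± 0.209 CPM in the mutant against 13.8 ± 2.19 in WT (SD, n = 3, log2 fold change -4.48 ± 0.34 SE, adjusted p = 4.95e-06). PAD3 was at 121 ± 4.31 against 301 ± 41.5 CPM (-1.31, adjusted p = 0.000288), and ABCG40 at 242 ± 11.8 against 508 ± 92.7 CPM (-1.07). The terpene synthase gene TPS04 was at 3.67 ± 0.725 against 22.2 ± 6.73 CPM (-2.59), and CYP82C2, an enzyme of indole metabolism, at 1.5 ± 0.528 against 14.1 ± 2.63 CPM (-3.22). WRKY60 was higher, at 44.2 ± 4.93 against 10.5 ± 0.534 CPM (2.06, adjusted p = 5.5e-08), and ICS1, an enzyme of salicylic acid synthesis, at 82.2 ± 9.67 against 29.5 ± 5.05 CPM (1.48, adjusted p = 0.000119). MRD1 (7.09) and HEI10 (3.29), which overlap, AMY1 (2.93) and CRK37 (2.43) were higher as well. AT3G41979, annotated as a ribosomal RNA gene, was at 6.99 CPM against 0.0142 CPM.

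Cysteine-rich receptor kinases were higher in 7 of 12 cases (median 0.81; 10 adjusted over the list alone), with CRK20 at 299 ± 39.6 against 145 ± 16.7 CPM and CRK10 at 452 ± 32.5 against 220 ± 8.74 CPM. ER folding genes were higher in 8 of 11 cases (0.48; 9 adjusted over the list alone), but in 0, 2 and 5 without WT replicates 1, 2 and 3 and in 1 without mutant replicate 2. The cysteine-rich receptor kinases numbered 4 without WT replicate 1 or 2 and 3 without mutant replicate 2. Higher were also salicylic acid genes in 3 of 20 (0.45; 6 adjusted over the list alone) with SARD4 at 0.76, and indole glucosinolate genes in 2 of 17 (0.31; 6 adjusted over the list alone) with IGMT1 at 0.62. Flavonoid genes were higher in 1 of 11 cases by either count (0.31), the gene being CHS (1.23), and photosynthesis genes were lower in 3 of 21 (-0.21; 7 adjusted over the list alone; 6 by total reads), with LHCB4.2 at -0.58. The photosynthesis genes numbered 1 without WT replicate 2 or mutant replicates 1 or 2 and 6 without mutant replicate 3, and the indole glucosinolate genes 1 without any 1 library but WT replicate 3. These 6 lists had adjusted p = 0.586 with an estimated correlation. Other WRKY genes were higher in 5 of 29 cases (0.15; 7 adjusted over the list alone), with WRKY71 at 1.39, and root markers in 1 of 13 (0.41; 4 adjusted over the list alone), the gene being PHO1 (0.52). Camalexin genes were lower in 3 of 10 cases by either count (median -0.10, mean -0.67), and phenylpropanoid genes in 4 of 13 (-0.23; 2 higher and 6 lower adjusted over the list alone), with F5H at -0.69. These 4 lists had adjusted p = 0.71 with an estimated correlation. By fry, only the cysteine-rich receptor kinases passed of these 10 lists (adjusted p = 0.014). The phenylpropanoid count was 1 without WT replicates 1 or 3 or mutant replicates 1 or 3, and 2 without mutant replicate 2. The call was lost without any 1 of 4 libraries for camalexin (adjusted p up to 0.12) and root markers (up to 0.0933, each without WT replicate 3). It was lost without any 1 of 3 for phenylpropanoid genes (up to 0.17, without mutant replicate 3) and of 2 for flavonoids (up to 0.098, without WT replicate 2), and 2 root markers were higher without WT replicate 2. Camalexin also lost its call by total reads (0.0512). Without both libraries that stood apart it was lost for camalexin (0.0809) and phenylpropanoid genes (0.153).

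The other 15 lists did not pass after flg22 (adjusted p = 0.125 to 0.886), but jasmonate passed without WT replicate 2 (0.0241) and tryptophan biosynthesis without mutant replicate 1 (0.0268). Pattern receptor genes were higher in 2 and lower in 5 of 25 cases (5 and 5 adjusted over the list alone), with PROPEP1 at -1.57 and PROPEP2 at -1.04. The flg22 markers held 1 higher and 1 lower gene of 9 (1 and 2 adjusted over the list alone), and jasmonate genes 1 higher and 3 lower of 26 (1 and 6 adjusted over the list alone), with JAR1 at 0.52 and ACX1 at -0.57. Abscisic acid genes held 1 higher and 1 lower of 14 (2 and 6 adjusted over the list alone), ethylene genes 1 higher of 20 (3 higher and 2 lower adjusted over the list alone), the gene being ACS7 (0.76), and auxin genes 1 lower of 13 by either count. Calcium genes were higher in 2 of 12 cases (2 higher and 1 lower adjusted over the list alone), clock genes in 2 of 13 (4 higher and 1 lower adjusted over the list alone) and NLR genes in 1 of 12 by either count. No gene passed by either count among tryptophan biosynthesis, aliphatic glucosinolates, secretion, the cell cycle, touch response and reference genes. The touch list had a median of 0.06 and a mean of -0.09. Without any 1 library the higher pattern receptor genes numbered 0 or 1 and the higher flg22 markers 0. No auxin gene was lower without mutant replicate 2, and 2 abscisic acid genes were without mutant replicate 3. Lower jasmonate genes numbered 5 by total reads and 1 without any 1 library but WT replicate 2. Calcium genes numbered 1 by total reads, by reference genes and without replicates 1 or 2 of either genotype, and clock genes 1 without replicates 1 or 3 of either.

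In total 1026 genes differed after flg22, 579 higher and 447 lower in the mutant, of which 114 and 86 differed at least 2-fold. By total reads more genes were lower (532 against 517 higher), and without WT replicate 3 more of the 2-fold ones were (113 against 106). The count was 499 without mutant replicate 2, 635 without mutant replicate 1 and 606 without WT replicate 1. Among the genes changed by flg22 in WT, 866 differed by genotype after flg22, against 736 for independent lists, with 346 that rose in WT and were higher in the mutant (195 if independent) and 273 that rose and were lower (150 if independent). A further 134 fell in WT and were higher in the mutant (221 if independent), and 113 fell and were lower (170 if independent). This count was 430 without mutant replicate 2, 505 without WT replicate 1 and 544 without mutant replicate 1. The log2 fold changes correlated at -0.081 with a covariance of -0.055, against a correlation of -0.532 and a covariance of -0.038 (-0.043 to -0.034) in 20 simulated runs with the treated WT libraries in common and 0 shared calls. The shared treated WT libraries enter the 2 comparisons with opposite signs. Their noise could add genes that rose in WT and were lower in the mutant, but not genes that rose and were higher. These libraries were too few to split.

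The interaction tested whether the change after flg22 differed between the genotypes. WRKY33 and WRKY40 rose less in the mutant, with interaction log2 fold changes of -3.55 ± 0.19 and -2.02 ± 0.29 (SE, adjusted p = 5.88e-07 and 0.00327), while WRKY18 did not pass (0.31 ± 0.33, adjusted p = 0.701). PAD3 rose less (-1.62 ± 0.26, adjusted p = 0.00636), as did BIP3 (-2.69 ± 0.36, adjusted p = 0.00254), which started higher in the mutant. The peroxidase gene PRX52 (-2.73), the RING finger gene AT2G44578 (-3.04), ACA12 (-2.00) and CML41 (-2.55) had negative terms, the last with 3.47 and 4.70 CPM in WT and 14.2 and 3.28 CPM in the mutant before and after flg22. WRKY60 fell less in the mutant (1.25 ± 0.14, adjusted p = 0.000946), and AT2G38430 (4.33), the GTPase gene ARFD1A (2.52) and the transcription factor gene AT3G10040 (2.14) had positive terms. Without both libraries that stood apart, ARFD1A (adjusted p = 0.0704) and CML41 (0.0525) no longer passed. RD29A had a term of 1.00, from 97.9 to 10.9 CPM in WT and from 38.6 to 8.66 CPM in the mutant.

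Phenylpropanoid genes had lower terms in 7 of 13 cases (median -0.57; 9 adjusted over the list alone), but in 3 with RLE factors, 4 by reference genes and 2 or 3 without any 1 library but untreated WT replicate 3, treated WT replicate 2 and untreated mutant replicate 3, with 4CL2 at -0.88 and CAD5 at -0.75, and pattern receptor genes in 4 of 25 (-0.43; 14 adjusted over the list alone). The flg22 markers had lower terms in 2 of 9 cases (-0.83; 6 adjusted over the list alone), with ATL2 at -0.88, and camalexin genes in 1 of 10 (-0.79; 7 adjusted over the list alone). Ethylene genes had lower terms in 4 of 20 cases (median -0.16, mean -0.54; 7 adjusted over the list alone), with ERF105 at -1.77, ERF104 at -1.29 and ERF5 at -1, and touch genes in 2 of 5 by either count (-1.02), with CML38 at -1.34. These 6 lists had adjusted p = 0.29 with an estimated correlation. Their genotype medians were all above 0 in untreated seedlings. After flg22 these were -0.23 for phenylpropanoids, 0 for pattern receptors and -0.10 for flg22 markers. They were -0.10 for camalexin, 0.07 for ethylene and 0.06 for touch genes, so the lower terms partly reflect higher levels in the untreated mutant. The lists of jasmonate (3 of 26 lower, median -0.36; 1 higher and 8 lower adjusted over the list alone), with AOC3 at -0.87 and ACX1 at -0.75, and NLR genes (2 of 12, -0.27; 3 adjusted over the list alone) passed too. So did other WRKY genes (1 higher and 2 lower of 29, -0.45; 2 and 7 adjusted over the list alone), with WRKY75 at -1.37, salicylic acid genes (2 of 20 lower, -0.36; 1 higher and 3 lower adjusted over the list alone), with PAD4 at -0.95, and aliphatic glucosinolate genes (1 of 12, -0.30; 3 adjusted over the list alone). Secretion genes (0 of 10, -0.24; 2 lower adjusted over the list alone), auxin genes (0 of 13, 0.25; 2 higher adjusted over the list alone) and cell cycle genes (0 of 10 by either count, 0.31) passed as lists. These 8 lists had adjusted p = 0.612 with an estimated correlation. By fry they did not pass (adjusted p = 0.185 to 0.463), while the 6 lists with 0.29 did (0.0387 each). By reference genes 1 gene each of other WRKY, salicylic acid and NLR genes had a lower term. Without untreated WT replicate 3 the lower terms numbered 8 for pattern receptors, 4 for flg22 markers, 5 for camalexin, 7 for ethylene, 6 for jasmonate, 4 for NLR genes, 5 for other WRKY genes, 7 for salicylic acid and 3 for aliphatic glucosinolates. With another library left out instead they numbered 0 to 5, 1 or 2, 1 or 2, 3 or 4, 2 or 3, 0 to 2, 1 or 2, 1 or 2 and 0 to 2, and touch genes 1 or 2. Pattern receptor genes numbered 0 without untreated WT replicate 1 or treated mutant replicate 2.

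The interaction calls of several lists were lost without 1 library. The adjusted p was 0.269 for secretion, 0.423 for the cell cycle, 0.0853 for other WRKY genes and 0.0607 for salicylic acid without replicate 2 of the untreated mutant. It was 0.125 for auxin without replicate 2 of untreated WT, and 0.139 for aliphatic glucosinolates without replicate 3 of treated WT. These are the highest values, from 6 libraries that each ended the call of secretion, 5 of the cell cycle, 4 of auxin and 2 each of aliphatic glucosinolates and other WRKY genes. Without both libraries that stood apart, jasmonate (0.0767) and NLR genes (0.115) lost their calls as well, beside other WRKY genes and the cell cycle (0.243 each), salicylic acid (0.133), auxin (0.156) and secretion (0.585). Secretion also lost its call with a replicate block (0.0589). The 11 lists that did not pass (adjusted p = 0.0535 to 0.885) included calcium (2 of 12 lower; 3 adjusted over the list alone), ER folding (2 of 11 lower by either count), with CRT3 at -0.66, flavonoids (1 of 11 higher by either count, but 0 by reference genes and without any 1 of 9 libraries) and abscisic acid (1 of 14 higher; 2 higher and 3 lower adjusted over the list alone). No gene passed by either count among tryptophan biosynthesis, indole glucosinolates, cysteine-rich receptor kinases, photosynthesis genes, the clock, root markers and reference genes, though 2 indole glucosinolate genes, 1 receptor kinase and 1 clock gene did without replicate 3 of untreated WT. The calcium list passed without untreated WT replicates 1 (adjusted p = 0.0442) or 3 (0.00845), treated WT replicate 2 (0.0433), untreated mutant replicate 3 (0.0176) or treated mutant replicate 1 (0.0183). The ER folding list passed without untreated WT replicate 1 (0.0442) or treated mutant replicate 2 (0.000773).

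In total 427 genes had an interaction, 82 higher and 345 lower, of which 32 and 153 were at least 2-fold. Of the 345 genes with a lower term, 290 rose with flg22 in WT. A smaller rise in the mutant than in WT was counted for 258 of the 345. Only 246 of the 345 passed the threshold as a rise in the mutant, so some of these smaller rises did not pass there. Of the same 345 genes, 229 were higher in the untreated mutant, 135 were lower in the mutant after flg22, and 36 were both. Of the 82 with a higher term, 48 were higher in the mutant after flg22 and 25 were lower in it before. The term is the genotype difference after flg22 minus that in untreated seedlings, from the same libraries. Genes called by it are thereby selected for such levels and for smaller or larger rises. These counts therefore describe the called genes and are no separate result. The count of 427 moved over 1.5 times without 1 library. It was 172 without replicate 1 of untreated WT, 181 without replicate 2 and 990 without replicate 3, and 250 and 255 without replicates 1 and 3 of treated WT. It was 243 without replicate 2 of the untreated mutant, and 213, 177 and 235 without replicates 1, 2 and 3 of the treated mutant.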

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

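For the genes beside the mutated loci and for the untreated mutant, the tests of a local lesion, of read depth, of single libraries, of handling and of time of day were chosen after the result was seen, as was the fit without 2 libraries. The criteria for handling and for time of day were also revised after their results were seen. Under the first wording the touch genes would have counted as bearing handling out, and the clock genes as arguing against time of day.

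The flg22 response differed between the genotypes by the interaction test for 427 genes, a count that ran from 172 (without untreated WT replicate 1) to 990 (without untreated WT replicate 3). The interaction log2 fold changes were 4.33 for AT2G38430, 2.52 for ARFD1A, 2.14 for AT3G10040, 1.25 for WRKY60 and 1.00 for RD29A. They were -3.55 for WRKY33, -2.02 for WRKY40, -1.37 for WRKY75, -3.04 for AT2G44578, -2.73 for PRX52 and -0.88 for ATL2. They were -0.95 for PAD4, -0.87 for AOC3, -0.75 for ACX1, -1.77 for ERF105, -1.29 for ERF104 and -1 for ERF5. They were -1.62 for PAD3, -0.88 for 4CL2, -0.75 for CAD5, -2.55 for CML41, -2.00 for ACA12, -2.69 for BIP3, -0.66 for CRT3 and -1.34 for CML38.

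Other named genes had interaction terms whose calls ended without 1 library, given with the highest adjusted p. Without untreated WT replicate 2 these were F5H (-0.71, adjusted p = 0.112), JAZ5 (-0.88, 0.096), PUB24 (-0.70, 0.101) and FLS2 (-0.50, 0.0736). Without untreated WT replicate 1 they were PR5 (-1.56, 0.122), MPK11 (-1.16, 0.139), WRKY28 (-0.78, 0.103), C4H (-0.60, 0.0699) and PROPEP1 (-2.15, 0.062). Without treated WT replicate 2 they were AT5G01790 (2.01, 0.111), CHS (1.03, 0.0996) and PDF1.2a (-4.02, 0.141), and without treated WT replicate 3 AT4G10500 (-2.96, 0.125). Without treated mutant replicate 2 they were BCAT4 (-0.87, 0.0787), ADR1 (-1.02, 0.0805), TCH4 (-1.02, 0.0853) and CYP77B1 (2.08, 0.0777), and without treated mutant replicate 3 TPPE (1.61, 0.0627). Without untreated mutant replicate 3 they were CYP82C2 (-3.77, 0.14) and TPS04 (-3.62, 0.0545).

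The lists with an interaction had median log2 fold changes of -0.45 for other WRKY genes, -0.43 for pattern receptors and -0.83 for flg22 markers. The medians were -0.36 for both salicylic acid and jasmonate, -0.16 for ethylene, -0.79 for camalexin, -0.30 for aliphatic glucosinolates and -0.57 for phenylpropanoid genes. They were 0.25 for auxin, -0.27 for NLR genes, -0.24 for secretion, 0.31 for the cell cycle and -1.02 for touch response. With an estimated correlation 0 of these lists passed, and without 1 library secretion (adjusted p = 0.269), the cell cycle (0.423), other WRKY genes (0.0853), salicylic acid (0.0607, each without untreated mutant replicate 2), auxin (0.125, without untreated WT replicate 2) and aliphatic glucosinolates (0.139, without treated WT replicate 3) did not.

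Reads outside genes, which no comparison used, took 2.944% of the reads in treated WT and 2.671% in the treated mutant, against 1.648% and 1.672% untreated. All 6 treated libraries lay above all 6 untreated ones (exact two-sided permutation test over 924 splits, p = 0.00216).

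Other splits of the libraries were counted for each test. For each comparison of 3 against 3 libraries 1 of the 10 splits, the real one, called as many genes, which is too few splits for a share under 0.05. The real counts were 14858, 14651, 2218 and 1026 genes for flg22 in WT, flg22 in the mutant, genotype untreated and genotype after flg22, and the highest of the other splits called 0 in each. For the interaction 2 of 100 drawn splits, the real one included, called as many genes as the real 427. The highest other split called 2710. That split exchanged the genotypes of all 6 treated libraries, so its term is the sum of both genotype effects, a structure of the samples. The remaining drawn splits mixed the genotypes within groups, which adds the genotype difference to the spread and can lower the calls. The share of splits therefore cannot decide on chance.

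A first pattern was the loss of reads from genes beside WRKY33 and WRKY18 in the mutant. Of the tested genes at least 8-fold lower in both genotype comparisons, the mutated genes left out, 4 of 4 lay within 20 kb of a mutated gene, as do 34 of 20584 genes (one-sided Fisher exact p = 6.2e-12). Too few reads to measure them is argued against, since each had at least 316 reads over the 6 WT libraries. A local lesion or linked variant at the mutated loci cannot be told apart from lower transcription there, since the genes were noticed by their position and counts do not separate the 2. A regulatory effect of the mutated WRKY genes on these neighbours stays open as untested.

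A second pattern was that the untreated mutant lay shifted in the direction of the WT flg22 response. For noise independent between genes, the shared untreated WT libraries are argued against as the whole cause, with a covariance of 0.301 against at most 0.036 in simulated runs. In the same way any 1 untreated library is argued against, since without 1 the covariance was at least 0.234 (without mutant replicate 2) and 0.275 (without WT replicate 2). Taken singly against the untreated WT mean, mutant replicates 1, 2 and 3 gave covariances of 0.211, 0.382 and 0.205. Shifts common to many genes of a library were not simulated, so the simulated range may be too narrow. The correlation, 0.397, was below the simulated mean of 0.465. Time of day at sampling cannot be told apart, because 1 of 13 clock genes passed (median absolute log2 fold change 0.18), but 3 did with RLE factors, 0 by reference genes and 4 without untreated WT replicate 3, where the clock list passed (adjusted p = 0.00214, against 0.0545 to 0.342 under the other alternatives). Those list results test a common direction only. Tested without regard to direction, fry gave the clock list an unadjusted p of 0.0436 between the untreated genotypes. Handling at sampling cannot be told apart, because 3 of 5 touch genes passed (1 without untreated WT replicate 1 or 2 or mutant replicate 2) and all 5 also rose with flg22 in WT. An effect of the genotype stays open as untested, and any such reading is a hypothesis from these data.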

How the results depend on the processing

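Scaling by total reads, scaling by reference genes and the fit without 2 libraries (untreated mutant replicate 2 and treated mutant replicate 3) were chosen after the data were seen, and the other alternatives were planned. Of 411 named gene results, 329 kept direction and side of the threshold under every alternative run, 80 lost the call under at least 1, 1 gained it, and WRKY18's interaction reversed, to -0.02 without the 2 libraries. Leaving out each library in turn ended 30 of 81 calls for genotype untreated, 21 of 58 for genotype after flg22 and 21 of 46 for the interaction. For flg22 it ended 3 of 113 calls in WT and 2 of 111 in the mutant. The flg22 counts ranged from 13908 to 16665 genes in WT and from 13588 to 16682 in the mutant over all alternatives, and from 14097 to 14360 and 13692 to 14434 without 1 library. The untreated genotype count was 850 without the 2 libraries and 902 to 2815 without 1, the count after flg22 was 499 to 775 without 1 library, and the WT flg22 genes that differ by genotype after flg22 numbered 430 to 1126 without 1 library and 1232 with DESeq2. The interaction count was 214 with a replicate block, 856 with DESeq2, 166 without the 2 libraries and 172 to 990 without 1. The lists called with an estimated correlation were 0 for flg22 in WT, 0 for flg22 in the mutant, 0 for genotype untreated, 0 for genotype after flg22 and 0 for the interaction, against 20, 19, 20, 10 and 14. By fry the numbers in the same order were 22, 21, 15, 1 and 6. Without the 2 libraries 7 lists were called for the interaction with the preset correlation. The cause was not tested for any of these changes. Replicate numbers did not pair the libraries, with a mean correlation of -0.033 over 18 pairs. Leaving out 1 library left 2 in its group. In simulated counts the interaction test recovered 18% of genes changed 1.5-fold, so small differences can be missed at this depth and number of replicates.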

Other observations

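Further genes beside the mutated loci, chosen after their values were seen, differed between the genotypes. Within 20 kb of WRKY40, J8 (1.12), CCR2 (1.12) and NRAMP1 (0.44) were higher in the untreated mutant. AT1G80850, which overlaps WRKY40, was higher after flg22 (0.85). The other tested genes there passed in neither genotype comparison. AT4G31790, beside WRKY18, was higher in the mutant after flg22 (0.84). Whether position mattered for these genes was not tested. The kinase gene CIPK22, beyond AT2G38480 on chromosome 2, was at 6.15 ± 1.09 CPM in the untreated mutant against 1.07 ± 0.0845 in WT (SD, n = 3, log2 fold change 2.53), and at 34.9 ± 0.958 against 11.7 ± 1.51 CPM after flg22 (1.57). AT2G38480, which overlaps the end of WRKY33 on the opposite strand, was at 8.73 ± 1.37 against 2.49 ± 0.0902 CPM after flg22 (1.81), a value that the overlap leaves uncertain. AT4G31810, which overlaps the end of AT4G31805 on the opposite strand of chromosome 4, was lower in the mutant, at 9.99 ± 1.16 against 18.2 ± 1.23 CPM untreated (-0.87) and 7.40 ± 1.49 against 12.0 ± 1.97 CPM after flg22 (-0.70), values that the overlap leaves uncertain.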
